A study of Mus musculus with 2 samples.

How the data were processed

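Bone marrow niche cells of adult mice were measured by droplet single-cell RNA sequencing in 2 libraries, 1 from LepR-Cre;tdTomato+ cells (group LepR_tdT) and 1 from bone marrow endothelial cells (group EC). The sample numbers in the protocol text overlap and no gate is stated, so the stains and sorting of these libraries are uncertain and the populations are taken from the labels. The deposited matrix holds raw UMI counts (unique molecular identifiers, each a counted molecule) for 27999 genes and all barcodes of both libraries, empty droplets included. The authors' cell table gives the library, the UMI count and the gene count of each cell. Cell Ranger 2.1.1, Seurat 2.3.4 and the mm10 genome build are named per the submitters' processing notes, which give no roles. The table held 4536 EC cells and 4250 LepR_tdT cells, the smallest with 201 genes. Recomputed UMI and gene numbers matched the table for 4536 EC cells and 4250 LepR_tdT cells. The table carries no cell type names, so classes were made here.

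All cells of the table were clustered together. UMIs were scaled to 10000 per cell and logged, and the 2000 most variable of all genes were taken. From these, genes seen in fewer than 10 cells, genes of the niche factors and Notch ligands lists, mitochondrial genes and tdTomato were removed. This left 1578 genes. These were scaled (maximum 10), reduced to 30 principal components and joined in a graph of 15 nearest neighbours. Leiden clustering by modularity at resolution 0.5 was run with 20 seeds and the clustering of highest modularity was kept. Clusters were named from fixed sets of cell type markers. A name needed at least 3 markers of the set with 1.5-fold or higher levels than in all other cells, at least 10 UMIs each. Cluster names stayed open where another set supplied more of the 10 leading genes than the candidate set, where at least 3 leading genes were mitochondrial, or where the median depth lay below the library's divided by 3 and no own marker led. The choice of the best of 20 seeds, the demand that a leading gene be seen in at least 10% of a cluster's cells, and the mitochondrial rule were added after the clusters had been seen. Endothelial-like clusters were called arterial-like or sinusoidal-like from subclass markers with a fold of at least 2. The names are candidates from RNA, hence "like".

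For each class the UMIs of its cells were summed and expressed per 1000000 UMIs of that class (CPM). With 1 library per group there is no replicate, and no test, p-value or count of changed genes was drawn from cells. Sums carry exact Poisson 95% intervals, ratios the conditional exact binomial interval, and shares of cells the exact Clopper-Pearson interval. These intervals cover counting error only, not variation between animals or preparations. A class with fewer than 3 UMIs of a gene was set to a floor of 3 UMIs in list medians, and a fold against 0 UMIs is given as a lower bound at that floor. The floor is summed over the class and equals 0.211 CPM in stromal-like, 0.233 in endothelial-like, 3.44 in arterial-like, 0.251 in sinusoidal-like and 2.27 in osteolineage-like cells.

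The comparisons, the gene lists, the markers, the rule for named genes and the first set of alternatives were chosen before the data were examined. The 17 lists were niche factors, Notch ligands, haematopoietic adhesion, chemokines and cytokines, adipogenic, osteogenic, interstitial matrix, basement membrane, endothelial junction, angiogenic receptors, scavenger receptors, antigen presentation, interferon response, BMP and Wnt modulators, immediate early and dissociation, proliferation, and growth factor ligands. A member was measured when the compared classes together held at least 20 UMIs of it. It was called higher in a class at a fold of at least 2 with an interval that excluded no difference. The list's median log2 ratio was placed among 10000 random lists of the same size matched on mean expression (from the 50 nearest genes), as a description of these libraries. The interval of the niche factor median comes from 10000 Poisson draws of the counts. Named genes were the measured niche factors and Notch ligands, the 10 highest and 10 lowest ratios of each comparison among genes with at least 100 CPM in the higher class, up to 4 members per other list with the most extreme ratios, and Lepr, Cdh5 and tdTomato as label checks. The 3 members of each marker set with the most UMIs were also named. Mitochondrial, ribosomal protein, haemoglobin and predicted genes were left out of the ranked genes. Within a library, genes used by the clustering are not read as results, since they helped to define the classes. The comparison of cluster 8 with stromal-like cells was added after the clusters had been seen.

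Positions come from GENCODE M21 on GRCm38, in which 27722 of the 27999 gene identifiers were found. Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, igraph 0.11.9, scikit-image 0.26.0 and matplotlib 3.10.9, and in R 4.3.3 with edgeR 4.0.16.

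The method was tested on simulated data made from the stromal-like, endothelial-like, arterial-like, sinusoidal-like and osteolineage-like profiles. Class sums were drawn from Poisson distributions around the pooled profile of each comparison, which is the model that the intervals assume. Coverage near 95% was therefore built in, and the check covers the calculation only. The simulation held no variation between cells, doublets or free RNA, so its rates may not hold for the real counts. The 95% intervals covered the true ratio for 95.6% of genes between stromal-like and endothelial-like cells, 96.5% between arterial-like and sinusoidal-like cells and 96.4% between osteolineage-like and stromal-like cells. Of genes changed 2-fold, 93.3%, 68.0% and 76.4% were recovered in these comparisons, and 46 of 12661, 106 of 10872 and 100 of 11561 unchanged genes were called 2-fold. At 4-fold the shares recovered were 98.6%, 93.0% and 90.3%.

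Alternatives covered which barcodes and cells enter, their depth, how cells are combined, scaling (edgeR TMM, median ratio of genes), low counts, free RNA, doublets and clustering. Free RNA was estimated from barcodes with 10 or fewer UMIs and scaled by markers that a class was assumed to lack. Stromal markers were uneven in sinusoidal-like cells, with Foxc1 at 9.99% and Lpl at 7.15% of the stromal-like level against 0.0516% for Adipoq. The share of free RNA may therefore be put too high there, above all by summed markers. The planned scaling by summed markers put free RNA at 29.2% of osteolineage-like UMIs, against 2.53% when the median marker set the scale, and the latter was added after that value was seen. Scrublet marked 0 EC cells and 1 LepR_tdT cell as doublets, so leaving out the 5% of cells with the highest scores was added. Also added after seeing the data were the handling of the mitochondrial, stress-led and Kit-bearing clusters, the mitochondrial limit and the removal of barcode sequences held by cells of both libraries. For named genes, an alternative gave no value where a class fell below 3 UMIs.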

Results

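Adult bone marrow niche cells of mice aged 3 to 4 months were profiled cell by cell in 2 droplet libraries, with 1 library for each labelled population and thus no replicates. Both came from LepR-Cre;LSL-tdTomato mice, in which cells that have expressed the leptin receptor, and their descendants, carry the red fluorescent protein tdTomato. The LepR_tdT library held tdTomato-positive stromal cells, which line marrow sinusoids and supply haematopoietic stem cells with growth factors. The EC library held endothelial cells, the lining of the marrow vessels. The LepR_tdT library counted 21983361 UMIs, of which 18139911 (82.5%) lay in 4250 cells with a median of 4347 UMIs and 1903 genes. The EC library counted 18152304 UMIs, of which 14111524 (77.7%) lay in 4536 cells with a median of 3084.5 UMIs and 1435 genes. The median mitochondrial share was 2.27% in LepR_tdT cells and 3.90% in EC cells. The design text aimed at 2000 to 3000 cells per sample.

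Most cells of each library carried the RNA markers of the population that its label names. LepR+ stromal-like cells made up 69.9% of the LepR_tdT library (95% interval 68.5 to 71.3, 2972 of 4250 cells), and endothelial-like cells made up 81.1% of the EC library (79.9 to 82.2, 3679 of 4536 cells). Osteolineage-like cells, led by the bone matrix genes Bglap, Postn and Col1a1, were 5.81% of LepR_tdT cells (5.13 to 6.56, 247 cells). Among endothelial-like cells of the EC library, 93.2% (92.4 to 94.0, 3430 cells) were sinusoidal-like and 6.77% (5.98 to 7.63, 249 cells) were arterial-like. The sinusoidal-like cells fell into 2 clusters, 1 of 2041 cells led by Sema3a, Ackr1 and Stab2, the other of 1389 cells led by the stress and adhesion genes Apold1, Klf4, Sele, Selp and Hspa1a. Small populations in the LepR_tdT library were endothelial-like cells (1.44%, 1.10 to 1.84, 61 cells) and pericyte-like cells with Rgs5 and Acta2 (0.400%, 0.233 to 0.640, 17 cells). Erythroid-like cells were 1.85% of EC and 0.447% of LepR_tdT cells, and granulocyte-like cells 0.882% and 0.565%. Shallow cells in clusters led by mitochondrial genes stayed unnamed. Cluster 4 held 16.1% of EC and 0.871% of LepR_tdT cells, with a median of 565 UMIs, and cluster 5 held 0.0441% and 15.1%, with a median of 518 UMIs. A further stromal cluster of 232 cells (5.46% of LepR_tdT, 4.79 to 6.18) was kept out of the stromal-like class because its leading genes included the progenitor marker Kit and the chondrocyte marker Comp but no stromal marker. The share of arterial-like cells moved with the clustering and the depth, to 12.9% at double the resolution, 10.9% without the stress-led cluster and 4.28% after thinning to 1000 UMIs per cell. At double the resolution none of the other endothelial-like clusters met the rule for sinusoidal-like cells, so that class depends on the resolution. With the stress-led cluster left unnamed but its cells still counted in the library, endothelial-like cells were 50.5% of the EC library. This share and the 10.9% are built into that setting.

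**Figure D1:**
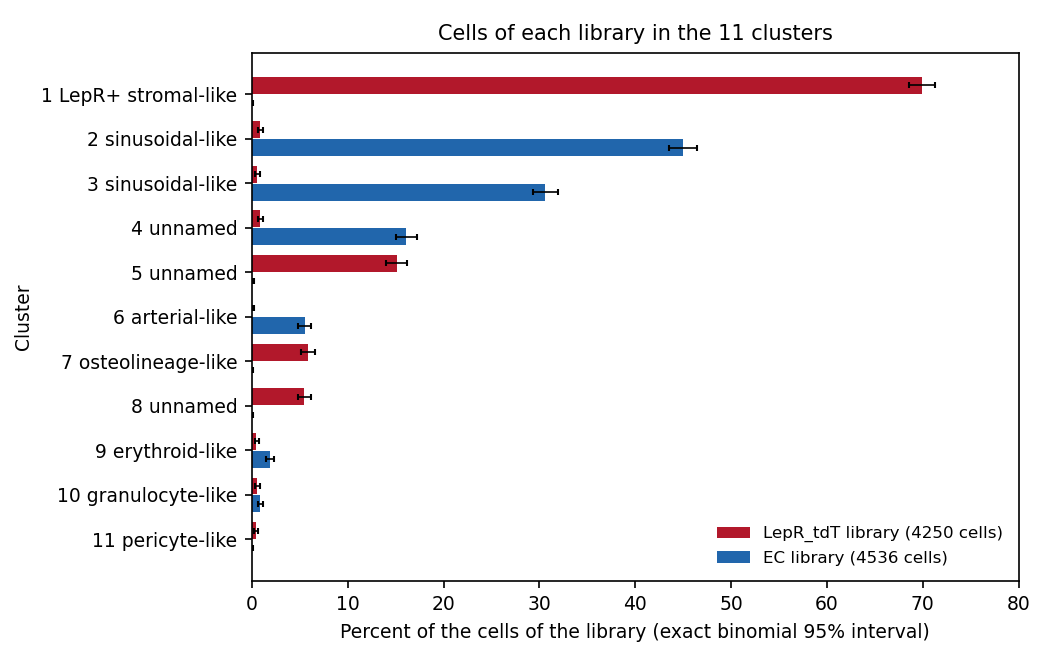
Bars give the percent of cells of each library (EC and LepR_tdT) in each of 11 clusters, with 95% Clopper-Pearson intervals. Cluster 1, LepR+ stromal-like, held 69.9% of LepR_tdT cells and none of the EC cells, and cluster 2, sinusoidal-like, held 45.0% of EC cells.

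Genes of the labelled populations, of which Lepr and Cdh5 were also naming markers, separated the libraries. Lepr, the leptin receptor (ENSMUSG00000057722, GRCm38 chromosome 4, 101717404 to 101815352), stood at 662 CPM (649 to 676) in stromal-like cells and 16.7 CPM (14.6 to 19.1) in endothelial-like cells, a log2 ratio of 5.31 (5.11 to 5.51). Within the EC library Lepr lay at 17.7 CPM (15.4 to 20.3) in sinusoidal-like, 3.44 CPM (0.708 to 10.04) in arterial-like, 9.82 CPM (2.02 to 28.7) in erythroid-like and 17.6 CPM (7.58 to 34.6) in granulocyte-like cells, beside 18.4 CPM in free RNA. Cdh5, which encodes VE-cadherin (ENSMUSG00000031871, chromosome 8, 104101625 to 104144511), showed the opposite, with 838 CPM in endothelial-like and 1.06 CPM in stromal-like cells and a log2 ratio of -9.63 (-10.47 to -8.91). The tdTomato transcript was captured at a low level, 278 UMIs in stromal-like against 24 UMIs in endothelial-like cells, a log2 ratio of 3.39 (2.79 to 4.06).

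Which cell type carries the factors that maintain haematopoietic stem and progenitor cells was the main question of the contrast between stromal-like and endothelial-like cells. Most niche factors were far higher in stromal-like cells. Cxcl12, the chemokine that retains stem cells in the marrow (ENSMUSG00000061353, chromosome 6, 117168535 to 117181367), reached 36308 CPM (36209 to 36407) in the 2972 stromal-like cells against 71.4 CPM (66.9 to 76.2) in the 3679 endothelial-like cells, 508-fold higher (476 to 543). Kitl, which encodes stem cell factor (ENSMUSG00000019966, chromosome 10, 100015630 to 100100416), was 97.1-fold higher (80.3 to 118), at 816 against 8.41 CPM. Of the endothelial-like UMIs, 85 of 108 for Kitl and 585 of 918 for Cxcl12 lay in the 249 arterial-like cells, so the class level describes neither subclass. Of 20 measured niche factors, 17 were higher in stromal-like cells, 1 in endothelial-like cells and 2 in neither, with a median log2 ratio of 4.03 (3.73 to 4.24) that lay at percentile 100 of random matched lists. Il7, the interleukin needed by B cell precursors, had a log2 ratio of 7.87 (6.64 to 9.50), and the macrophage growth factor Csf1 one of 4.34 (4.17 to 4.52). Gas6, a ligand of TAM receptors that also served as a stromal marker in naming, had 5.49 (5.42 to 5.57), and Mdk, which encodes midkine, 7.58 (7.09 to 8.12). Osteopontin (Spp1, ENSMUSG00000029304, chromosome 5, 104435118 to 104441050) stood at 5919 against 1.17 CPM, a log2 ratio of 12.31 (11.59 to 13.15).

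Some niche factors were all but missing from endothelial-like cells. Angpt1, the ligand of the Tie2 receptor, had 1561 UMIs in stromal-like and 0 in endothelial-like cells, at least 471-fold higher, and Ptn, which encodes pleiotrophin, had 60 and 0, at least 18.1-fold higher. Il34 had 8717 UMIs against 2 (log2 ratio 11.94, 10.09 to 14.99) and Lif 49 against 1 (5.47, 2.92 to 10.80). Smaller ratios were seen for Igf1 (3.33), Il15 (2.35), Il6 (1.84), Bmp4 (1.75), Rarres2 (1.69) and Flt3l (1.60). Tgfb1, a cytokine that restrains stem cell cycling, was the exception, 5.07-fold higher (4.72 to 5.46) in endothelial-like cells at 324 against 63.8 CPM. Vcam1, an adhesion molecule for stem cells (ENSMUSG00000027962, chromosome 3, 116109949 to 116129688), was as high in both classes, at 1954 CPM (1931 to 1977) and 1960 CPM (1936 to 1984). Pros1 also differed by less than 2-fold, with a log2 ratio of -0.33 (-0.41 to -0.25).

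**Figure D2:**
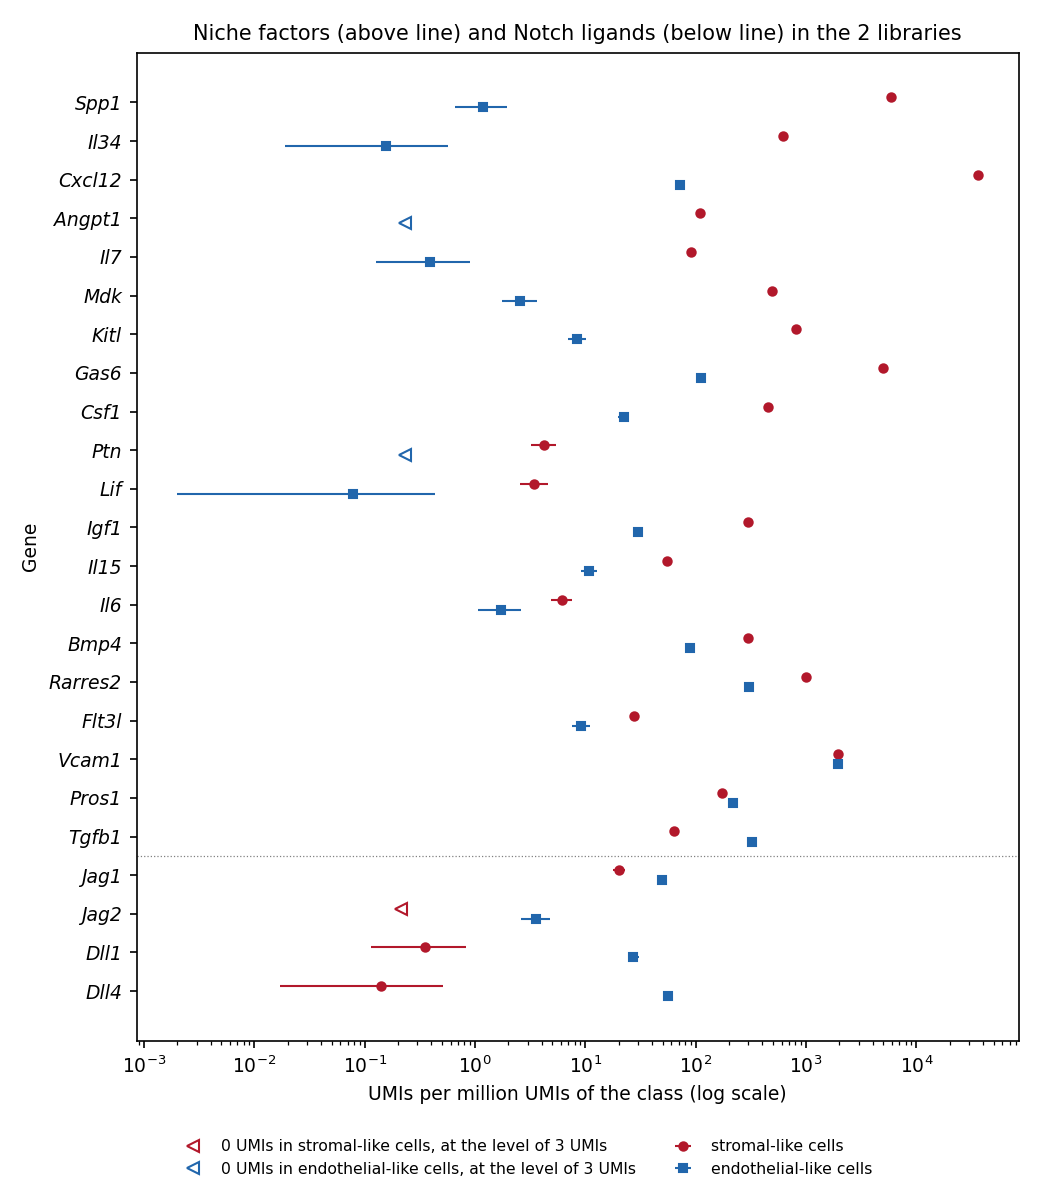
UMIs per 1000000 (CPM) on a log axis for 20 niche factors and 4 Notch ligands in stromal-like cells of LepR_tdT (circles) and endothelial-like cells of EC (squares), with exact Poisson 95% intervals; open triangles mark 0 UMIs, drawn at the level of 3 UMIs. Cxcl12 stood at 36308 against 71.4 CPM, whereas Dll4 stood at 0.141 against 56.2 CPM.

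Notch ligands, which act on neighbouring blood cells, showed the reverse, with all 4 higher in endothelial-like cells (median log2 ratio -5.18, percentile 0.06). Dll4 (ENSMUSG00000027314, chromosome 2, 119325784 to 119335962) had 722 UMIs in endothelial-like and 2 in stromal-like cells, 399-fold higher (110.1 to 3302). Dll1 was 77.4-fold higher (32.9 to 239.9), and Jag2 (ENSMUSG00000002799, chromosome 12, 112907819 to 112929776) had 46 UMIs against 0, at least 17.0-fold higher. Jag1 (ENSMUSG00000027276, chromosome 2, 137081456 to 137116644) was 2.46-fold higher (2.14 to 2.84), and its counts also varied within each library along with other genes that hold long runs of T, with a log2 ratio of 1.47 between cells at the ends of that axis in LepR_tdT. Among 13 measured haematopoietic adhesion genes, 4 were higher in stromal-like and 7 in endothelial-like cells (median -1.29, percentile 0.02). The vascular selectins Sele and Selp, on which circulating leukocytes roll, had log2 ratios of -9.56 and -9.16. Of 14 chemokines and cytokines, 9 were higher in stromal-like and 1 in endothelial-like cells (median 3.64, percentile 100), with Cxcl14 at 11.05 and Ccl19, a ligand of CCR7, at 9.08. Tnfsf11, the osteoclast factor RANKL, had 1198 UMIs against 0, at least 361-fold higher in stromal-like cells.

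As a class, stromal-like cells carried adipogenic and osteogenic transcripts together. The osteogenic list had 13 of 14 measured members higher in these cells and 1 in neither (median 7.02, percentile 100), among them Ibsp, which encodes bone sialoprotein (11.64), and the collagen gene Col1a2 (10.98). Wif1, a secreted Wnt inhibitor, had 4125 UMIs against 0, at least 1244-fold higher. Of 11 adipogenic genes, 6 were higher in stromal-like and 4 in endothelial-like cells (median 2.07, percentile 100). Adipoq, Lepr, Lpl and Cebpa on this list were stromal naming markers, so their direction is no separate result and the list median partly rests on them. The adipokine Adipoq (ENSMUSG00000022878, chromosome 16, 23146536 to 23158028), a naming marker, had a log2 ratio of 11.02 (10.32 to 11.83) and Agt, which encodes angiotensinogen, 11.84. The fatty acid binding protein Fabp4 (ENSMUSG00000062515, chromosome 3, 10204088 to 10208576) went the other way with -7.76 (-7.85 to -7.67), at 15916 CPM in endothelial-like cells, as did adipsin (Cfd, -7.29). Interstitial matrix genes were higher in stromal-like cells for 16 of 20 members and in endothelial-like cells for 2 (median 8.65, percentile 100), with Serping1 at 11.17. BMP and Wnt modulators had 16 of 17 members higher in stromal-like cells and 1 in endothelial-like cells (median 5.90, percentile 100), with Sfrp4 at 10.59, the naming marker Chrdl1 at 10.34 and the activin inhibitor Fst at 10.27. Basement membrane genes split, 3 higher in stromal-like and 4 in endothelial-like cells of 13 (median 0.01, percentile 44.4), Lamb1 at 5.43 and Nid2 at 3.22 against perlecan (Hspg2) at -3.24 and Col15a1 at -3.05. Growth factor ligands were higher in stromal-like cells for 10 of 18 members and in endothelial-like cells for 4 (median 1.42, percentile 99.99). Fgf7 stood at 8.85, the lymphangiogenic factor Vegfc at 6.09 and Pdgfb, which recruits pericytes, at -8.24.

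Endothelial junction genes were higher in endothelial-like cells for 8 of 9 members (median -6.68, percentile 0), with Esam at -9.18, Cldn5 at -9.03 and F11r at -8.23. Angiogenic receptors were higher there for 13 of 15 members and in neither for 2 (median -2.95, percentile 0), including the VEGF receptors Flt4 (-9.71) and Kdr (-8.83), Robo4 (-9.34) and Tek (-9.11), the receptor of the Angpt1 protein. Scavenger receptors, which clear blood-borne waste in sinusoids, were higher there for 8 of 10 members and in stromal-like cells for 2 (median -6.95, percentile 0). Fcgr2b was at -10.58, Stab2 at -9.37 and the mannose receptor Mrc1 at -9.11, whereas Lrp1 had 2812 UMIs in stromal-like cells against 0, at least 848-fold higher. Other genes with low ratios were the atypical chemokine receptor Ackr1 (-10.15), Clca3a1 (-9.76), Rasip1 (-9.69), Grrp1 (-9.39) and the DNase gene Dnase1l3 (-9.72, ENSMUSG00000025279, chromosome 14, 7964533 to 7994573). Esam, Cldn5, Kdr, Robo4, Tek, Flt4, Fcgr2b, Stab2, Mrc1 and Dnase1l3 were naming markers of the endothelial or sinusoidal sets, so their direction is no separate result. Within the EC library, Dnase1l3 also differed by 0.79 log2 along the axis of genes with T runs, and Cxcl12 (-0.56), Csf1 (-0.58) and Bmp4 (-0.39) differed the other way. Endothelial subclasses were pooled for these values. At the other end stood Tnc, which encodes tenascin C (12814 UMIs against 1, log2 ratio 13.50, 11.02 to 18.80), the chemokine scavenger Ackr4 (11.71) and Gpx8 (11.39).

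Immune and stress genes divided less sharply. Antigen presentation genes were higher in stromal-like cells for 3 of 12 members and in endothelial-like cells for 3 (median 0.57, percentile 96.4), the class I gene H2-D1 at 2.02, against the class II genes H2-Aa at -3.11 and Cd74 at -2.39. Of 14 interferon response genes, 5 were higher in stromal-like and 1 in endothelial-like cells (median 0.78, percentile 99.8), with Ifit1 at 3.02, Isg15 at 1.94 and Rsad2 at -2.33. Immediate early and dissociation genes, which respond to tissue digestion, were higher in each class for 3 of 15 members (median -0.22, percentile 34.4), Egr1 at 1.99 against Hspa1b at -2.90 and Atf3 at -2.27. Proliferation genes were higher in endothelial-like cells for 5 of 9 members and in neither for 4 (median -1.03, percentile 1.38), with Cdk1 at -2.83, Stmn1 at -1.73 and Top2a at -1.26. The granulocyte gene S100a8 moved the same way, at 72.7 CPM in endothelial-like cells (21.1% of cells) and 18.6 CPM in stromal-like cells (6.49%), whereas the erythroid gene Hbb-bs stood at 138.8 and 115.3 CPM. With 1 library per population these ratios carry counting error only, and between the libraries preparation and population cannot be separated. Subtracting free RNA gave Cxcl12 a log2 ratio of 9.93, and leaving out the stress-led cluster gave Kitl 5.98 and the niche factors a median of 3.45. Within the LepR_tdT library, 61 endothelial-like cells held Cxcl12 at 1882 CPM (1698 to 2081), against 36308 CPM in stromal-like cells. The direction for Cxcl12 was thus the same within 1 preparation. The size of that difference is uncertain, since free RNA of this library held Cxcl12 at 16563 CPM.

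Within the EC library, the comparison of arterial-like with sinusoidal-like cells asked which vessels hold niche factors. Kitl was 50.7-fold higher (31.7 to 84.2) in arterial-like cells, at 97.3 CPM (77.8 to 120.4) against 1.92 CPM (1.22 to 2.88), from 85 and 23 UMIs in 249 and 3430 cells. Cxcl12 was 24.1-fold higher, at 669.9 against 27.8 CPM, a log2 ratio of 4.59 (4.39 to 4.79). A Cxcl12 UMI was seen in 39.8% of arterial-like and 8.43% of sinusoidal-like cells (median depths 3162 and 3409.5 UMIs), against 1 of 40 granulocyte-like (10640 UMIs) and 1 of 84 erythroid-like cells (843 UMIs), which should lack it. Thinned to 1000 UMIs per cell, with 24, 49, 0 and 46 shallower cells left out, the shares were 27.6%, 2.57% (2.07 to 3.16), 0 of 40 (up to 8.81%) and 0 of 38 (up to 9.25%), which does not separate sinusoidal-like from these blood cells at that depth. Whether the sinusoidal-like Cxcl12 UMIs came from these cells, from free RNA or from stromal RNA carried along with them was left open. In the other direction, Vcam1 was 3.45-fold higher (3.16 to 3.77) in sinusoidal-like cells, and Rarres2, which encodes chemerin, had a log2 ratio of -3.45 (-4.07 to -2.90), Bmp4 -2.37 (-3.18 to -1.66) and Igf1 -3.20 (-5.48 to -1.64).

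Across 14 measured niche factors, 2 were higher in arterial-like and 4 in sinusoidal-like cells and 8 in neither (median 0.21, percentile 56.8), the last group including Tgfb1 (0.35), Gas6 (0.07), Csf1 (0.04) and Pros1 (-0.09). Notch ligands split, with Jag2 9.65-fold higher (5.07 to 18.0) in arterial-like cells, Jag1 2.84-fold higher in sinusoidal-like cells (log2 ratio -1.51, -2.32 to -0.79), and Dll4 (0.63, 0.26 to 0.98) and Dll1 (0.31) in neither (median 0.47, percentile 85.3). Scaling by TMM would lower every log2 ratio of this comparison by 0.15 and scaling by the median ratio by 0.14, so ratios below these sizes have no settled direction. Cdh5 had a log2 ratio of 0.20 (0.09 to 0.30).

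Basement membrane genes were higher in arterial-like cells for 7 of 13 members and in sinusoidal-like cells for 0 (median 1.87, percentile 100), with the laminin gene Lamb1 at 5.73, Col15a1 at 5.24 and the nidogen gene Nid2 at 3.42. Of 12 haematopoietic adhesion genes, 7 were higher in arterial-like and 4 in sinusoidal-like cells (median 1.13, percentile 100), with Jam2 at 5.26, Podxl at 3.33 and Lama4 at 2.99 against Selp at -2.14. The clustering used 3 of these 12 genes and 2 of the 13 basement membrane genes. Interferon response genes were higher in arterial-like cells for 8 of 14 members and in neither for 6 (median 1.21, percentile 100), with Oasl2 at 1.35, although 6 of the 14 were used by the clustering. The 4 antigen presentation genes that were higher, out of 12 (median 0.43, percentile 98.2), were all used by the clustering and are no separate result. Adipogenic genes were higher in sinusoidal-like cells for 4 of 9 members (median -0.95, percentile 0.03), 2 of the 9 being used by the clustering, with Cebpb at -1.49. Scavenger receptors were split 2 and 2 out of 8 (median -0.36, percentile 0.50), Msr1 at 2.67 and Scarb1 at 1.32 against the sinusoidal naming markers Stab2 and Mrc1. Endothelial junction genes (2 of 9 higher in arterial-like cells, median 0.34, percentile 94.2) included Pecam1 at 1.12. Angiogenic receptors (3 higher in arterial-like and 1 in sinusoidal-like cells of 15, median 0.08, percentile 34.95) included Notch4 at 1.66 and the VEGF receptor Flt1 at 1.12. Growth factor ligands were higher in arterial-like cells for 7 of 15 and in sinusoidal-like cells for 4 (median 0.44, percentile 97.7), 7 of the 15 being used by the clustering, with Vegfc at 3.92.

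Interstitial matrix genes (2 higher in each class of 9, median 0.81, percentile 99.6) ran from Serpinf1 at 4.16 to Col6a3 at -2.14, with 3 of the 9 used by the clustering. Chemokines and cytokines (3 and 2 of 9, median -0.11, percentile 11.5) ran from fractalkine (Cx3cl1) at 1.97 to Tslp at -1.54, with 5 of the 9 used by the clustering. BMP and Wnt modulators (1 and 1 of 5, median 0.59, percentile 93.7) included Fstl1 at 2.48. No osteogenic gene of 2 (median 0.29) and no proliferation gene of 8 (median 0.21, 6 used by the clustering) passed the 2-fold limit. Of 15 immediate early and dissociation genes, 1 was higher in sinusoidal-like cells (median -0.24, percentile 1.59), Socs3 at -1.11, and 7 of the 15 were used by the clustering. Socs3 and Zfp36 (-0.96) both turned, to 0.59 and 0.64, when the stress-led cluster was left out. Among the highest ratios were the transcription factor gene Tcf15 (6.76, 5.89 to 7.76), Lims2 (5.57), the taurine transporter gene Slc6a6 (4.87), Plcb1 (4.68) and Adgre5 (3.88). The lowest included the virus and adhesion receptor gene Cxadr (-3.13), Mmrn1 (-2.35), the transcription factor gene Irf8 (-2.28) and Prelp (-2.23). The Kitl ratio rested on 23 sinusoidal-like UMIs, and moved from 5.66 (4.98 to 6.40) to 6.49 after thinning. Subtracting free RNA gave 7.57 by the median marker and at least 8.54 by summed markers. The latter is a lower bound at the floor, since that subtraction left no sinusoidal-like Kitl UMIs.

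**Figure D3:**
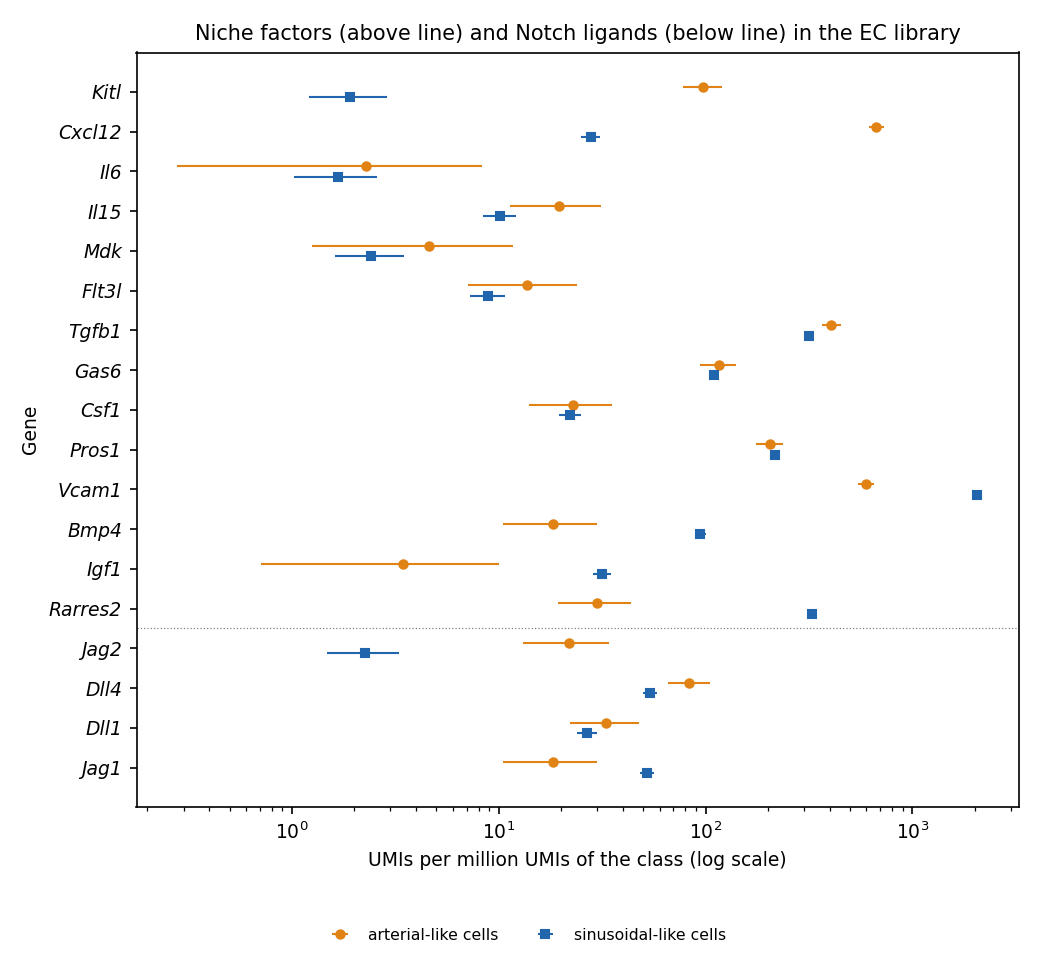
UMIs per 1000000 (CPM) on a log axis for 14 niche factors and 4 Notch ligands in arterial-like (circles) and sinusoidal-like (squares) cells of the EC library, with exact Poisson 95% intervals. Kitl stood at 97.3 against 1.92 CPM and Jag2 at 21.8 against 2.25 CPM, while Vcam1 stood at 597 against 2059 CPM.

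Within the LepR_tdT library, osteolineage-like cells were compared with stromal-like cells. Cxcl12 was 2.74-fold lower (2.70 to 2.79), at 13234 CPM (13038 to 13432) in 247 osteolineage-like cells, a log2 ratio of -1.46 (-1.48 to -1.43), but at clustering resolution 1.0 this ratio was -0.93, short of the 2-fold limit. Kitl was 2.35-fold lower (2.14 to 2.59). Of 20 niche factors, 4 were higher in osteolineage-like and 9 in stromal-like cells (median -0.66, percentile 0). Among the lower ones were Il34 (-2.57), Bmp4 (-2.46), Angpt1 (-1.82), Il15 (-1.72), Gas6 (-1.40), Il7 (-1.15) and Rarres2 (-1.01). The 4 higher ones were osteopontin (Spp1, 6.01-fold, 5.94 to 6.08), Lif (2.40), Ptn (1.98) and Tgfb1 (1.26), and Jag1, the only measured Notch ligand, had 1.15 (0.72 to 1.55). Free RNA of this library held Cxcl12 at 16563 CPM, above the osteolineage-like level. Subtracting free RNA moved the Cxcl12 log2 ratio only to -1.49 by the median marker and -1.67 by summed markers. The erythroid gene Hbb-bs was also higher in osteolineage-like cells, at 1280 against 115.3 CPM, although seen in 20.6% and 22.9% of cells, whereas the granulocyte gene S100a8 stood at 15.9 and 18.6 CPM.

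Genes of the adipocyte lineage were lower in osteolineage-like cells, 7 of 11 adipogenic members with none higher (median -1.36, percentile 0), such as Pparg at -2.69. Lepr itself had -1.55 (-1.72 to -1.38). However, 3 of the 11 were used by the clustering, and Adipoq, Lepr, Lpl and Cebpa were naming markers of the stromal-like class, so the list is partly no separate result. Osteogenic genes were higher for 12 of 14 (median 2.19, percentile 100) and interstitial matrix genes for 8 of 19 (median 0.90, percentile 100). However, 9 members of each list were used by the clustering, and of the others Col6a3 stood at 3.52. Runx2, Sp7, Alpl, Col1a1, Bglap, Ibsp, Dmp1 and Wif1 on the osteogenic list were also naming markers of the osteolineage-like class. The direction of that list is thus largely no separate result. Chemokines and cytokines (2 higher and 5 lower of 14, median -0.78, percentile 0) included the alarmin gene Il33 at 5.68, and 9 of its members were used by the clustering. Basement membrane genes (1 and 4 of 12, median -0.68, percentile 0) ran from Hspg2 at 1.17 to Col4a1 and Nid2, both at -1.25. Interferon response genes were lower for 5 of 14 (median -0.60, percentile 0.01), with Irf7 at -1.07, and 6 of the 14 were used by the clustering. BMP and Wnt modulators (2 and 6 of 17, median -0.35, percentile 0.57) ran from noggin (Nog) at 2.36 to Sfrp2 at -2.62 and Chrdl1 at -2.31. Growth factor ligands were lower for 4 of 14 (median -0.63, percentile 0), with Vegfc at -1.64 and Angpt2 at -1.44, and 6 of the 14 were used by the clustering. Angiogenic receptors (2 and 3 of 10, median -0.43, percentile 1.20) ran from Unc5b at 2.01 to Nrp1 at -1.18. Few members passed among endothelial junction genes (2 of 6 higher, median 0.58, with Cgnl1 at 1.66), haematopoietic adhesion genes (1 of 9 higher, median 0.11) and antigen presentation genes (1 and 1 of 11, median -0.53). The clustering used 2 of the 9 adhesion and 3 of the 11 antigen presentation genes. It also used 2 of the 12 basement membrane genes and 3 of the 17 BMP and Wnt modulators. No scavenger receptor of 5 (median 0.43), no immediate early gene of 15 (median 0.28, 7 used by the clustering) and no proliferation gene of 5 (median -0.22, 3 used) passed the limit. Beyond the lists, the gelatinase gene Mmp2 (4.16, 3.90 to 4.43), the osteoblast membrane gene Tmem119 (4.11), Wisp1 (3.48), Kcnk2 (3.08) and the transcription factor gene Mef2c (2.75) were among the highest of the genes not used by the clustering. Cbln1 (-4.12), Itih5 (-3.43), Efemp1 (-3.33), Slc26a7 (-2.87) and the kininogen gene Kng1 (-2.62) were among the lowest.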

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

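All tests in this part were chosen after the counts they measure had been seen. Outside the cell table, 42 EC barcodes and 25 LepR_tdT barcodes held at least 500 UMIs. No main comparison used them, and the alternative with all barcodes took in 35 EC and 20 LepR_tdT ones. Most of the 42 and 25 barcodes were rich in haemoglobin transcripts. These made up over 50% of the UMIs of 36 EC and 20 LepR_tdT barcodes. The medians were 89.0% and 91.4%, against 0.385% and 0.159% of the UMIs of the cells in the table. They held at most 186 and 159 genes.

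Cxcl12 UMIs in the EC library were weighed against 3 technical sources. Outside the cells of that library lay 3129 Cxcl12 UMIs, and 77.5% of them (76.0 to 78.9, 2424 UMIs) were at barcode sequences of LepR_tdT cells, which are 0.574% of the barcodes there, against 0.815% of the UMIs of the endothelial gene Cdh5. This is consistent with LepR_tdT molecules assigned to the EC library (0.406% of the Cxcl12 UMIs of LepR_tdT cells). In sinusoidal-like cells such molecules were excluded as the main source. Of the Cxcl12 UMIs there, 97.0% (94.5 to 98.6, 323 of 333) lay in cells whose barcode sequence is no LepR_tdT cell. Free RNA was not settled. Sinusoidal-like cells held 6.02 times as many Cxcl12 UMIs per cell (1.65 to 49.9) as 124 erythroid-like and granulocyte-like cells. These control cells held only 2, and most were shallow erythroid-like cells. EC free RNA held Cxcl12 at 592 CPM, against 27.8 CPM in sinusoidal-like cells. Taken at 592 CPM and put at 3.43% or 6.20% of sinusoidal-like UMIs, free RNA could supply most or all of this level. However, the 592 CPM may itself include molecules of LepR_tdT cells, given the 77.5% above, which would lower that supply. How many of them entered the free RNA was not measured. Stromal RNA carried along with sinusoidal-like cells cannot be told apart from expression, since Cxcl12 per Adipoq UMI was 1.48 times (0.900 to 2.63) that in stromal-like cells, while 2 of 15 stromal markers, Pdgfrb (0 UMIs, up to 0.0496% of the stromal-like level) and Hp (0.0493%), lay below the 0.0766% of Cxcl12. In arterial-like cells carried-along RNA was excluded, with 585 Cxcl12 UMIs against 0 of Adipoq, at least 13.9 times the stromal-like ratio at the floor of 3 UMIs (lower bound of the interval 11.3), which leaves expression there as a hypothesis.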

How the results depend on the processing

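No paired analysis was possible because each population has 1 library and no label pairs cells or animals. None of the 5 main log2 ratios turned under any alternative that gave a value. The following values moved beyond their counting interval, and unless stated the cause was not tested. The limit of at least 500 UMIs applied to all barcodes gave a niche factor median of 4.27, 71.3% stromal-like and 96.3% endothelial-like cells. It turned 3 named genes, Fabp4 in osteolineage-like cells (0.26), and Angpt1 (0.010) and Il6 (-0.11) in cluster 8. Cells with at least 2000 UMIs gave shares of 82.8% stromal-like, 97.6% endothelial-like and 5.47% arterial-like. The mean of cells gave Cxcl12 9.14 between stromal-like and endothelial-like cells and -1.41 in osteolineage-like cells, and turned Bmp2 between arterial-like and sinusoidal-like cells (-0.045). Thinning to 1000 UMIs gave Cxcl12 9.25 and -1.41, Kitl 7.16 and, between arterial-like and sinusoidal-like cells, 6.49, and shares of 81.7%, 97.8% and 4.28%. It turned Gja1 between these endothelial subclasses (-0.00849) and Hmgb2 in cluster 8 (0.15).

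Free RNA subtraction gave Cxcl12 9.93 and -1.67, Kitl 7.05 and, between endothelial subclasses, at least 8.54 (a bound at the floor), and 67.7% stromal-like cells. Scaled by the median marker, it gave Cxcl12 9.48 and -1.49, Kitl 7.57 between endothelial subclasses, and 68.0%. The Cxcl12 values 9.93 and 9.48 rest on EC free RNA that may hold misassigned LepR_tdT molecules, so they may be too high. In osteolineage-like cells Cxcl12 was -1.38 with TMM and -1.37 with the median ratio. All cells of each library gave a niche factor median of 4.41. Resolution 0.25 gave Cxcl12 -1.54 in osteolineage-like cells and 76.1% stromal-like cells, and turned Cd74 in osteolineage-like cells (-0.36). Resolution 1.0 gave a niche factor median of 3.47, Cxcl12 -0.93 in osteolineage-like cells (short of 2-fold), 48.4% stromal-like and 12.9% arterial-like cells, and turned Fabp4 in osteolineage-like cells (0.33). At that resolution no cluster met the rule for sinusoidal-like cells, so the comparison of endothelial subclasses, Kitl included, had no value. Other seeds gave Cxcl12 -1.52 in osteolineage-like cells.

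Alternatives added after seeing the data moved these. With the shallow clusters added, the shares of stromal-like, endothelial-like and arterial-like cells were 85.0%, 97.2% and 5.65%, a change built into that setting. With cluster 8 added, 75.4% of cells were stromal-like, also by construction. Without the stress-led cluster, Cxcl12 was 8.49, Kitl 5.98 and the niche factor median 3.45. The shifts of Cxcl12 and Kitl are partly built in. Arterial-like cells held 585 of 918 Cxcl12 and 85 of 108 Kitl UMIs of the endothelial-like class and made up more of it in this setting. The shares were 50.5% endothelial-like, with the cells of that cluster still counted in the library, and 10.9% arterial-like, both by construction. In the same setting Socs3 (0.59), Zfp36 (0.64) and Fosb (1.48) turned between the endothelial subclasses. Clustering without immediate early genes gave 8.93% arterial-like cells. A limit of 10% mitochondrial UMIs gave 74.4% stromal-like and 88.2% endothelial-like cells. Leaving out barcode sequences shared by cells of both libraries moved none of the 8 main results. Of 5412 values for 366 pairs of a named gene and a comparison under 20 settings, 4880 stayed within their interval, 521 moved and 11 turned. Depth limits the smaller classes most: in data simulated with Poisson counts only, 68.0% of 2-fold changes between arterial-like and sinusoidal-like cells were recovered.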

Other observations

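Of the tests in this part, the test of long transcripts was set before its result was seen, and the others, those of Kit, T runs and A runs, after. A stromal cluster of 232 LepR_tdT cells (cluster 8, median 5847.5 UMIs) was compared with the stromal-like cells. Of 11 adipogenic genes 3 were higher and 0 lower (median log2 ratio 0.68, percentile 100), with Fabp4 at 2.77 (2.63 to 2.91), and the lipid droplet gene Plin2 at 1.84. Of 14 osteogenic genes 4 were lower and 0 higher (median -0.70, percentile 0), such as the osteoblast transcription factor gene Sp7 at -1.42, but 9 of the 14 osteogenic and 3 of the 11 adipogenic genes were used by the clustering and 4 osteogenic genes lay at the floor. Cxcl12 was as high as in stromal-like cells (log2 ratio -0.01, -0.03 to 0.00) and Lepr nearly so (-0.20, -0.31 to -0.10). Of 20 niche factors 1 was higher and 2 lower (median 0.03, percentile 78.2). The higher one, Il6 at 1.46, turned to -0.11 (-0.84 to 0.57) with all barcodes of at least 500 UMIs classed by their marker UMIs. The lower ones were Bmp4 (-1.31) and Ptn, from 1 and 60 UMIs. Kitl (-0.68), Igf1 (0.79) and Vcam1 (0.52) stayed short of the 2-fold limit.

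Immediate early and dissociation genes were higher in cluster 8 for 9 of 15 members (median 1.12, percentile 100), 7 of the 15 being used by the clustering, with Atf3 at 2.36 and Zfp36 at 1.48 among the others. Outside the lists and the clustering, the neutrophil chemokine Cxcl5 (3.88), Cd300lg (3.77), the cyclooxygenase gene Ptgs1 (3.44), the lipid desaturase gene Scd1 (3.17) and Mrap (2.55) were among the highest. Htra1 (-2.48), the iron exporter gene Slc40a1 (-1.66), Podnl1 (-1.64), Notch3 (-1.59) and Lifr (-1.54) were among the lowest. Of 7 scavenger receptors 2 were higher (median 0.74, percentile 99.91), with Cd36 at 3.54. Growth factor ligands were lower for 3 of 14 members (median -0.31, 6 used by the clustering) and BMP and Wnt modulators for 2 of 17 (median -0.18). The medians of the remaining lists lay between -0.55 and 0.48.

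Kit, which encodes the stem cell factor receptor, was at 289.9 CPM in cluster 8 against 14.6 CPM in stromal-like cells (412 and 208 UMIs), a log2 ratio of 4.31 (4.06 to 4.56). The gene was used by the clustering and singled out after its values were seen. Doublets with haematopoietic progenitors were argued against, narrowly, by the other 6 progenitor markers, whose sum had a log2 ratio of -0.68 (-6.07 to 2.01) from 1 and 16 UMIs. In clusters made without Kit, 221 of the 232 cells stayed together in a cluster of 262. There Kit was 11.7-fold higher (8.78 to 15.97) than in 510 stromal-like cells with at least the 1.55% of immediate early UMIs of its median cell (13.3-fold with Kit in the clustering). A high share of immediate early UMIs alone thus did not bring Kit to this level. That clustering still used immediate early genes, so a stress programme that drew its own cells into the cluster was not excluded. Free RNA was excluded as the main source, since Kit CPM were 13.8 times (7.17 to 30.3) those of free RNA. A Kit-expressing stromal state is a hypothesis that these tests do not separate from such a stress programme.

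In endothelial-like cells of EC and in stromal-like cells of LepR_tdT, a block of genes varied together from cell to cell at matched depth, and a shared feature, runs of T in the transcript, was found by an exploratory search of sequence words over 8 run lengths. In cells in the top 25% against the bottom 25% of a 10-gene score, the other genes with a T run of at least 20 bases had a median log2 ratio of 0.131 in EC (325 genes, random lists -0.033 to 0.015) and 0.149 in LepR_tdT (338 genes, -0.032 to 0.012), which is consistent with a step that depends on such runs. Runs of A were argued against, with medians of -0.029 (-0.045 to -0.008) and -0.014 (-0.038 to 0.004). So was transcript length, with -0.043 (-0.061 to -0.012) and -0.047 (-0.077 to -0.030) for length-matched genes without T runs. The intervals of these medians come from 2000 bootstrap draws of genes. They measure spread between genes, taken as independent, and not counting error or variation between animals. Across genes, which are not independent replicates, the ratios of the libraries correlated at r = 0.595 (rho 0.248) over 1390 genes with runs of at least 12 bases and at r = 0.042 over 2544 genes with runs under 8. Along the axis differed Actb (1.81 in EC and 1.80 in LepR_tdT), Jag1 (0.60 and 1.47) and, in EC, Dnase1l3 (0.79) but not Cdh5 (-0.02). In EC, Cxcl12 (-0.56, -0.82 to -0.30), Csf1 (-0.58, -1.11 to -0.06) and Bmp4 (-0.39, -0.64 to -0.14) differed the other way. The EC values pool the endothelial subclasses, and 585 of 918 Cxcl12 UMIs lay in arterial-like cells. Whether subclasses were uneven along the axis was not tested. The step involved was not tested, and no biological explanation was tested.

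Markers of other cell types were summed over all cells of each library, as CPM in EC and LepR_tdT in that order. Among stromal sets, Hp had 33.1 and 8856, Gpx3 11.4 and 5796 and Gas6 106 and 4465. The osteolineage markers Ibsp, Mmp13 and Col1a1 had 2.98 and 6289, 0.0709 and 592, and 0.213 and 362. Of fibroblast markers, Dcn had 0.354 and 853, Ly6a, also an arterial marker, 478 and 24.4, and Fbn1 0.425 and 244. Chondrocyte markers were low, Comp at 0.0709 and 60.2, Sox9 at 0.0709 and 14.7 and Col2a1 at 0.142 and 9.43. Kcnj8 (621 and 14.1) and Abcc9 (577 and 21.8), known from pericytes, were higher in the EC library, where no pericyte-like cluster was found, and Myl9 had 1.98 and 225. Schwann cell markers were Ncam1 (1.84 and 115), Scn7a (0 and 6.89) and Mbp (6.59 and 0.662). Endothelial markers were Cldn5 (2463 and 43.0), Kdr (1064 and 14.7) and Egfl7 (1012 and 17.5), with the sinusoidal markers Tfpi (3594 and 99.1), Il6st (1857 and 136) and Stab2 (1471 and 16.9) and the arterial markers Fbln5 (58.4 and 1288) and Ly6c1 (253 and 7.28).

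Blood cell markers were also present. Granulocyte markers were S100a8 (1663 and 448), S100a9 (1129 and 389) and Camp (527 and 232), and erythroid markers Hbb-bs (1494 and 682), Hba-a1 (1137 and 407) and Hba-a2 (778 and 324). Monocyte markers were Ly6c2 (62.3 and 31.4), Vcan (0.354 and 19.1) and Ms4a6c (7.44 and 4.58). B lineage markers Vpreb3 (10.7 and 2.37), Igll1 (9.21 and 2.04) and Vpreb1 (8.43 and 2.59) and T or NK markers Nkg7 (15.8 and 8.16), Ccl5 (0.496 and 0.717) and Cd3d (0.213 and 0.0551) were low. The platelet markers Pf4 (54.3 and 265) and Ppbp (20.8 and 155) were higher in LepR_tdT and Clec1b (43.7 and 19.3) in EC. Basophil or mast cell markers Prss34 (70.9 and 0), Mcpt8 (68.1 and 0) and Cpa3 (4.11 and 0) had 0 UMIs in LepR_tdT. Plasmacytoid dendritic cell markers Tcf4 (776 and 156) and Bst2 (545 and 304) are also expressed by endothelium, and Ccr9 had 0.283 and 4.63. The progenitor markers Kit (10.8 and 37.3), Spi1 (10.9 and 6.23) and Cd53 (7.23 and 3.31) were low.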
